A study of Mus musculus with 12 samples.

How the data were processed

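Gene expression was measured on 12 Illumina bead arrays, 3 for each combination of ALI day (3 or 9) and shRNA (Myb or scrambled). Groups and replicate numbers were taken from the labels. Total RNA was labelled as biotinylated antisense RNA, per the labels' protocols. The deposited table of unnormalised values gives, per the file headers, an intensity (signal) and a detection p-value for each of 45281 probes on each array. The values show that a background had been subtracted, since about 28.8% to 34.4% of signals per array lie below 0, with medians of 7.10 to 10.6 and highest values of 40900.6 to 54502. A second deposited table holds processed values on a log2 scale, whose medians are all about 6.02 and whose rank order equals that of the signal on each array (rank correlation 1). The offset and the normalisation behind it are not stated. BeadStudio 3.0 and limma are named in the submitters' processing notes, without a step or a model.

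The signals were processed in R 4.3.3 with limma 3.58.1. The function neqc corrected the background by a normal-exponential model whose negative controls are inferred from the detection p-values, added an offset of 16, normalised quantiles between arrays and took log2. Probes with a detection p-value under 0.01 on at least 3 arrays were kept, 15526 in all. Probes were named from the platform annotation, which can be old, and symbols were updated through a table of mouse genes (assembly GRCm38.p6, used for names only). By this route 28620 were named by Entrez ID, 2637 by accession, 2128 by a current symbol and 2343 by a synonym, while 56 kept the name given. The platform's annotation gives 35784 probes 1 symbol and 0 probes several, and 9497 are unnamed here. Of the probes kept, 13793 had a name and 1733 had none and were left out. For the 3182 genes with several probes the probe with the highest mean over all arrays was used, which left 9381 genes. Probes of 1 gene gave opposite calls for 2 genes at day 9 and 4 at day 3.

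A linear model of the 4 group means was fitted to all 12 arrays with lmFit, which gives 8 residual degrees of freedom, and moderated with eBayes with a trend on mean level (prior degrees of freedom 5.34). Contrasts were Myb shRNA against scrambled at day 9 and at day 3, day 9 against day 3 in each arm, and the interaction. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. The median SE of a difference was 0.167, and 0.237 for the interaction. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists tested. Camera with an estimated correlation and fry were run beside it. None of the 48 camera calls passed with an estimated correlation. Before the data were examined, 23 lists with 515 entries were fixed, 25 of which have no probe, and lists with under 5 measured genes (ionocyte, neuroendocrine, tuft and endothelial markers) were described only. The contrasts, the tests, the rule for named genes and the alternatives were fixed at the same point. The rule names, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap (no such condition for the interaction), leaving out genes known only by clone or number, up to 4 members of each list with the smallest p, and Myb. From the genes this rule gave, those whose calls held when any single array was left out were preferred in the text, after the results were seen.

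The replicate numbers were checked for pairing, by correlating across genes the deviations of arrays from their group means. In each comparison of groups, all arrays with the same number correlated above 0.1 (lowest 0.297 and 0.150 for the shRNAs at day 9 and day 3, and 0.267 and 0.107 for the days in scrambled and Myb shRNA), so the numbers were read as pairs for these comparisons, from the data and not from the labels. Over all groups 16 of 18 pairs lay above 0.1, the lowest at 0.0196, and so the interaction was not read as paired. The pairs below the bound were those of day 3 Myb shRNA replicates 1 and 2 with the day 9 scrambled arrays of the same number (0.0196 and 0.0617). The correlation averaged 0.265, 0.228 and 0.490 for arrays numbered 1, 2 and 3. It averaged 0.256 (0.131 to 0.477) between arrays numbered 1 and 2, and -0.350 between those numbered 3 and the others. On average the data thus set number 3 apart and do not tell number 1 from number 2. The pairing of these was read only by the bound of 0.1, though 10 of 12 arrays correlated best with their own number. Day 3 Myb shRNA replicate 1 correlated at 0.150, 0.0196 and 0.107 with arrays numbered 1 and 0.232, 0.173 and 0.161 with those numbered 2. Replicate 2 correlated at 0.477, 0.375 and 0.415 with arrays numbered 1 and 0.265, 0.0617 and 0.245 with those numbered 2. No fit was made with these numbers exchanged. Fits with the replicate number as a block are given beside the counts. Unless a block is named, p-values are from the fit without it, which does not use the pairing. The slide of each array is not given in the sources used here.

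The code was tested on simulated data with 200 changed genes among 9381. For Myb shRNA against scrambled at day 9, 41.8%, 91.0% and 100% of genes changed by 1.5, 2 and 4-fold were recovered, with 10 false calls. For day 9 against day 3 in Myb shRNA, 34.3%, 92.5% and 100% were recovered with 6 false calls, and for the interaction 11.9%, 71.6% and 98.5% with 4. Camera called 0 of 50 unchanged simulated lists. The simulated noise was independent between genes and arrays. These checks therefore do not show how the fit and camera behave with correlated genes or with deviations that arrays share. Quality was checked by principal components, of which the first 3 hold 59.1%, 17.1% and 7.60% of the variance, by correlations between replicates of 0.971 to 0.994, and by a search for identical arrays, which found 0 pairs; 13247 to 15100 probes (29.3% to 33.3%) were detected per array.

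Alternatives were no background correction, the submitters' processed values, centring on the 75th percentile, no detection filter, detection on all 12 arrays, the mean of a gene's probes, eBayes without a trend, array weights, the replicate block, only the 6 arrays of the groups compared, a 2-fold minimum, and leaving out each array in turn. Leaving out all 4 arrays numbered 3 was added after these arrays were seen to stand apart.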

Results

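Primary tracheal epithelial cells from male C57BL/6J mice were grown on porous membranes at an air-liquid interface (ALI), a culture in which basal progenitor cells build an epithelium of ciliated and secretory cells. The cells carried a lentiviral shRNA against Myb, which encodes a transcription factor of progenitor cells, or a scrambled control shRNA. Total RNA from day 3 and day 9 of ALI was measured on Illumina bead arrays. The 12 arrays form 4 groups of 3 biological replicates: day 3 scrambled, day 3 Myb shRNA, day 9 scrambled and day 9 Myb shRNA. The number of arrays limits the precision of every value. After a filter on detection, 9381 genes were tested. Levels are log2 normalised intensities with SD (n = 3 per group), differences are on the log2 scale with SE, and p-values are limma's, adjusted by Benjamini-Hochberg. Where a gene was not well above background on any array of a group, its difference between groups is given as a bound: the other group's mean over the lowest level at which a probe counted as detected on the dim group's arrays, or the dim probe's own level if higher. The interaction of day and shRNA is given without such a bound.

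Myb, the targeted gene, was at background on nearly all arrays. None of its 4 probes passed the detection filter, and the single detection was on 1 array, day 3 scrambled replicate 3, where the signal of 1 probe was 84.6. In the other day 3 scrambled replicates the same probe read -26.1 and -31.0. The Myb probe with the highest mean read 5.42, 5.22 and 5.31 in the day 3 scrambled replicates and 4.95, 4.74 and 5.00 in the day 3 Myb shRNA replicates, which were all lower. At day 9 it read 5.10, 5.36 and 4.95 in scrambled and 5.12, 5.35 and 5.05 in Myb shRNA cultures. The probe with the single detection was lower on each Myb shRNA array than on any scrambled one at both days, at 4.28, 4.32 and 4.32 against 4.65, 4.71 and 4.95 at day 9, but these values lie at background (difference -0.46, adjusted p = 0.652 at day 9, and -0.82, adjusted p = 0.229 at day 3, in a fit of all probes). In a fit of all genes without the filter, with 1 probe per gene, the Myb difference was -0.41 ± 0.14 at day 3 (adjusted p = 0.0935) and 0.04 ± 0.14 at day 9 (adjusted p = 0.947). Those values are of the probe with the highest mean, whose adjusted p in the fit of all probes were 0.138 and 0.960. The arrays therefore do not check the knockdown, and the group names below follow the labels.

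The comparison of Myb shRNA with scrambled shRNA at day 9 asks which genes of the ALI epithelium depended on the shRNA at the later stage of culture. Genes of motile cilia fell. Of 27 measured motile axoneme genes, 23 fell and none rose (25 lower adjusted over the list alone). Rsph9, a radial spoke protein, fell from 11.98 ± 0.14 to 10.58 ± 0.30, Dynlrb2, a dynein light chain, from 13.67 ± 0.17 to 12.29 ± 0.33, and Enkur and Ak8, by 1.73 and 1.52. The list's median difference was -1.43 (camera adjusted p = 6.96e-19, adjusted p = 0.170 with an estimated correlation). Of 24 other ciliated cell markers, 19 fell (23 adjusted over the list alone), with a median of -1.42 (camera adjusted p = 1.01e-19, adjusted p = 0.155 with an estimated correlation). Morn5 fell by 1.83, Pifo by 1.65 and Capsl by 1.51. Factors that assemble dynein arms before they enter the cilium fell in 7 of 8 cases (8 adjusted over the list alone), such as Dnajb13 at -1.50 ± 0.24, Dnaaf3 at -1.34 ± 0.26 and Zmynd10 at -1.28 ± 0.22. These assembly factors had a median of -1.24 (camera adjusted p = 3.90e-07, adjusted p = 0.155 with an estimated correlation). Intraflagellar transport genes, which carry cargo along the cilium, fell in 11 of 18 cases (16 adjusted over the list alone), including Ift74 at -1.09 ± 0.16 and Ift27 at -0.98 ± 0.13. Intraflagellar transport genes had a median of -0.79 (camera adjusted p = 2.09e-11, adjusted p = 0.155 with an estimated correlation).

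Few genes upstream of the cilium passed at day 9. Of 9 measured regulators of multiciliogenesis, 1 fell, Ccdc78, at -1.12 ± 0.25 (adjusted p = 0.00681), and 3 were lower adjusted over the list alone. As a list they did not pass (median -0.42, camera adjusted p = 0.204). Rfx2, a transcription factor of ciliary genes, differed by -0.95 ± 0.31 (adjusted p = 0.0507, and 0.000159 with a replicate block). Centriole assembly genes fell in 4 of 14 cases (4 adjusted over the list alone), with Cep78 at -1.02 ± 0.18 and Cep97 at -0.95 ± 0.18, the latter detected on 1 of 3 Myb shRNA arrays. Centriole assembly genes had a median of -0.44 (camera adjusted p = 0.000281, adjusted p = 0.262 with an estimated correlation).

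Some basal and squamous genes rose at day 9. Of 21 basal cell markers, 7 rose and none fell (11 higher adjusted over the list alone), with a median of 0.47 (camera adjusted p = 3.00e-05, adjusted p = 0.281 with an estimated correlation). The membrane scaffold gene Cav1 rose from 7.88 ± 0.23 to 9.50 ± 0.24 and the laminin chains Lamb3 and Lama3 by 1.19 ± 0.20 and 0.87 ± 0.18. Squamous and cornified envelope genes rose in 7 of 15 cases (7 adjusted over the list alone), among them Tgm1, a transglutaminase that cross-links the envelope, at 1.72 ± 0.20 (2 of 3 scrambled arrays detected it), and the keratin Krt4 at 1.02 ± 0.17. Squamous genes as a list had a median of 0.71 (camera adjusted p = 0.000228, adjusted p = 0.155 with an estimated correlation). Targets of p53 rose in 4 of 18 cases (6 adjusted over the list alone), with Ccng1 at 0.86 ± 0.14 and Zmat3 at 0.75 ± 0.16. The p53 targets had a median of 0.46 (camera adjusted p = 0.00156, adjusted p = 0.170 with an estimated correlation).

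Secretory genes went both ways at day 9. The club cell secretoglobins Scgb1a1 and Scgb3a1 fell, from 10.09 ± 0.60 to 7.89 ± 0.16 and from 9.63 ± 0.11 to 7.87 ± 0.24, and the antimicrobial lectin gene Reg3g fell by 1.17. Of 20 club cell markers, however, 3 rose and 6 fell (4 and 6 adjusted over the list alone). The list did not pass by camera (median -0.02, camera adjusted p = 0.174), though fry passed it as lower (adjusted p = 0.0225). Goblet cell and mucus genes did not pass either (1 of 13 rose and 3 fell, 2 and 5 adjusted over the list alone, camera adjusted p = 0.125). Itln1, an intelectin, fell by 1.86 and Gp2 by 2.18, each detected on 1 of 3 Myb shRNA arrays. In Notch signalling, which sets the choice between ciliated and secretory fate, Hey1 and Hes6 fell by 1.81 and 1.49 while no other of 13 members passed, overall or over the list alone (camera adjusted p = 0.749). With a replicate block Jag2 passed too (adjusted p = 0.00467). The 20 luminal epithelial markers were split, with 4 higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.818). Krt7 rose by 0.92 and Prom1, detected on 2 of 3 Myb shRNA arrays, fell by 1.63.

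Lists of proliferation, immune and other cell types did not pass at day 9. The camera adjusted p was 0.125 for cell cycle and mitosis (1 of 18 rose, 0 adjusted over the list alone), 0.304 for S phase and DNA replication (1 of 23, Rrm1, rose by 0.83) and 0.304 for the interferon response (1 of 18 rose and 3 fell, Usp18 by 0.84). It was 0.846 for inflammation and acute phase (none of 10), 0.640 for fibroblast and smooth muscle markers (1 of 5, the matrix protein gene Sparc, rose by 1.56, while 1 more was lower adjusted over the list alone) and 0.651 for leukocyte markers (1 of 7 rose and 2 fell, the lysozymes Lyz1 and Lyz2, which airway gland cells also make). The other counts of these lists were the same adjusted over the list alone. Lists with under 5 measured genes were described only. Among them the tuft cell gene Gng13 fell by 1.86 and the ionocyte proton pump gene Atp6v1c2 fell by 1.11. The endothelial adhesion gene Esam rose by 1.96 with 2 of 3 scrambled arrays detecting it, and the neuroendocrine gene Uchl1 was below detection in both groups.

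The largest single rise at day 9 was that of Ager, a receptor abundant in alveolar type 1 cells, from 6.21 ± 0.14 to 10.68 ± 0.49 (adjusted p = 1.47e-05). Akap5, an anchoring protein, rose by 3.54 ± 0.32 from a scrambled group in which 1 of 3 arrays detected it. Ttll11, a tubulin glutamylase, rose by 2.46 ± 0.39, the sodium channel subunit Scnn1b by 2.16 ± 0.40, and Rasl11b, Acaa1b and Ogn by 2.42, 2.14 and 2.05. Col4a3, a basement membrane collagen, was not well above background on any scrambled array and was at least 4.20-fold higher (adjusted p = 0.000171). Large falls included those of Clca3b at -3.36 ± 0.30, Myl4 at -3.24 ± 0.26, Serpinb12 at -3.23 ± 0.48, and Diras2 at -3.13 ± 0.47. Other falls were those of Fam216b at -2.91 ± 0.37, the cilium genes Ttc29 at -2.89 ± 0.33 and Cfap161 at -2.72 ± 0.21, and Ampd1, an AMP deaminase, at -2.77 ± 0.22.

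In all, 1513 genes passed at day 9, 624 higher and 889 lower with Myb shRNA, or 16.1% of those tested. By comparison, 3441 genes (36.7%) had groups that did not overlap, against 10% by chance. The count was 2331 with the replicate number as a block (1147 higher and 1184 lower), and it was 948 without day 9 scrambled replicate 3 and 999 without day 9 Myb shRNA replicate 2. Median, mean and test differed in sign for luminal, Notch and interferon lists.

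The same comparison at day 3 asks which genes depended on the shRNA early in ALI culture, while the ciliated cell programme starts. Regulators of multiciliogenesis fell in 5 of 9 cases (5 adjusted over the list alone). These regulators had a median of -1.39 (camera adjusted p = 0.000244, adjusted p = 0.147 with an estimated correlation). Ccno, a cyclin needed for centriole amplification, fell from 12.09 ± 0.50 to 10.26 ± 0.25. Mcidas, a coregulator that starts the programme, fell from 8.59 ± 0.71 to 6.61 ± 0.35, and the transcription factor gene Foxn4 fell by 2.68 ± 0.26 with 1 of 3 Myb shRNA arrays detecting it. Ccdc78 was not well above background with Myb shRNA and was at least 2.00-fold lower (adjusted p = 0.00044). Centriole assembly genes fell in 8 of 14 cases (9 adjusted over the list alone), with Ccp110 at -1.45 ± 0.23, Cep78 at -1.31 ± 0.18 and Cep63 at -0.97 ± 0.15. Centriole assembly genes had a median of -0.67 (camera adjusted p = 1.20e-05, adjusted p = 0.146 with an estimated correlation).

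Most genes of ciliary structure fell at day 3. Motile axoneme genes fell in 20 of 27 cases (24 adjusted over the list alone), and Lrrc23, a radial spoke protein, fell from 10.49 ± 0.43 to 6.44 ± 0.34, Dynlrb2 from 12.62 ± 0.36 to 9.54 ± 0.16 and Tekt1, a tektin of the axonemal microtubules, by 3.83 ± 0.28. Motile axoneme genes had a median of -1.62 (camera adjusted p = 3.17e-18, adjusted p = 0.146 with an estimated correlation). Dynein arm assembly factors fell in 7 of 8 cases (8 adjusted over the list alone), with Dnaaf1 at -2.91 ± 0.30 and Zmynd10 at -3.21 ± 0.22, which 2 of 3 Myb shRNA arrays detected. These assembly factors had a median of -2.03 (camera adjusted p = 7.94e-09, adjusted p = 0.146 with an estimated correlation). Other ciliated cell markers fell in 20 of 24 cases (20 adjusted over the list alone), led by Morn5 at -3.85 ± 0.17 and Riiad1 at -2.87 ± 0.18. Other ciliated cell markers had a median of -2.08 (camera adjusted p = 1.47e-17, adjusted p = 0.146 with an estimated correlation). Intraflagellar transport genes fell in 8 of 18 cases (10 adjusted over the list alone), such as Ift22 at -1.71 ± 0.16. Intraflagellar transport genes had a median of -0.65 (camera adjusted p = 3.52e-07, adjusted p = 0.147 with an estimated correlation).

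Some basal, squamous and p53 genes were higher at day 3 as well. Of 21 basal cell markers, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.20e-05, adjusted p = 0.171 with an estimated correlation). Lama3 rose from 7.82 ± 0.29 to 9.56 ± 0.31, Lamb3 from 10.04 ± 0.17 to 11.76 ± 0.41 and the laminin receptor subunit Itga3 by 1.36 ± 0.16. Squamous genes rose in 5 of 15 cases (7 adjusted over the list alone), with the envelope proteins Sprr1a at 2.47 ± 0.27 and Ivl at 2.11 ± 0.37. Squamous genes as a list had a median of 0.44 (camera adjusted p = 0.00423, adjusted p = 0.146 with an estimated correlation). The squamous call was lost with detection on all 12 arrays and with array weights. Targets of p53 rose in 11 of 18 cases (12 higher and 1 lower adjusted over the list alone), including Zmat3 at 1.06 ± 0.16, Ccng1 at 0.97 ± 0.14 and Trp53inp1 at 0.70 ± 0.13. The p53 targets had a median of 0.52 (camera adjusted p = 2.35e-05, adjusted p = 0.146 with an estimated correlation). Club cell markers fell in 10 of 20 cases and 1 rose (10 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.0012, adjusted p = 0.146 with an estimated correlation). Scgb3a1 fell by 2.41, Reg3g by 1.61 and the aldehyde dehydrogenase Aldh1a7 by 1.40, while the secreted protein gene Bpifa1 rose by 0.84.

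Other genes with the largest rises at day 3 were Cdkn2a, which encodes cell cycle inhibitors, from 5.52 ± 0.53 to 8.52 ± 0.28 with 1 of 3 scrambled arrays detecting it, and Ager, by 2.41 ± 0.35. The growth factor binding protein gene Igfbp2 rose by 2.57 ± 0.27 and Spon2 by 2.45 ± 0.18, with 1 and 2 of 3 scrambled arrays detecting them. Sema3c and the mucin gene Muc16 were not well above background on any scrambled array and were at least 3.11-fold and 4.00-fold higher (adjusted p = 0.00677 and 0.000179). Cfap161, Ccna1, Tsnaxip1 and Ttc29 were not well above background on any Myb shRNA array and were at least 11.0-fold, 9.12-fold, 6.01-fold and 5.95-fold lower (adjusted p = 1.5e-07, 1.5e-07, 3.31e-06 and 1.08e-05). Among single genes of other lists, Hey1 fell by 2.10, the mitotic kinase genes Cdk1 and Aurka by 1.30 and 1.42, and Sparc and the matrix enzyme Lox rose by 1.98 and 1.28. The lists they belong to did not pass by camera: its adjusted p was 0.937 for Notch signalling (3 of 13 rose and 3 fell, 3 and 4 adjusted over the list alone), 0.958 for cell cycle and mitosis (1 of 18 rose and 3 fell) and 0.0704 for fibroblast and smooth muscle markers (2 of 5 rose). Counts of the latter lists were the same adjusted over the list alone. Of these lists, fry passed only the fibroblast and smooth muscle markers, as higher (adjusted p = 0.0017). Leukocyte markers (1 of 7 rose and 4 fell) did not pass by camera (adjusted p = 0.0704), but fry passed them as lower (adjusted p = 0.00132). Luminal markers (4 of 20 rose and 3 fell) did not pass by camera either (adjusted p = 0.178), while fry passed them as higher (adjusted p = 0.0418).

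At day 3, 2134 genes passed, 1081 higher and 1053 lower, or 22.7% of those tested, and 3431 genes (36.6%) had groups that did not overlap, against 10% by chance. With the replicate number as a block the count was 3400 (1775 higher and 1625 lower), and no single left-out array moved it by more than 1.5 times. Median, mean and test differed in sign for the Notch, cell cycle and interferon lists. Across genes, the differences at the days had a Pearson correlation of 0.681 and a Spearman correlation of 0.594. The comparisons share no array, and genes are not independent replicates. Of the genes past the threshold, 365 were higher at both days against 71.9 for independent lists, 538 were lower at both days against 99.8, and 12 went opposite ways, 4 of them higher at day 3 and 8 higher at day 9.

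**Figure D1:**
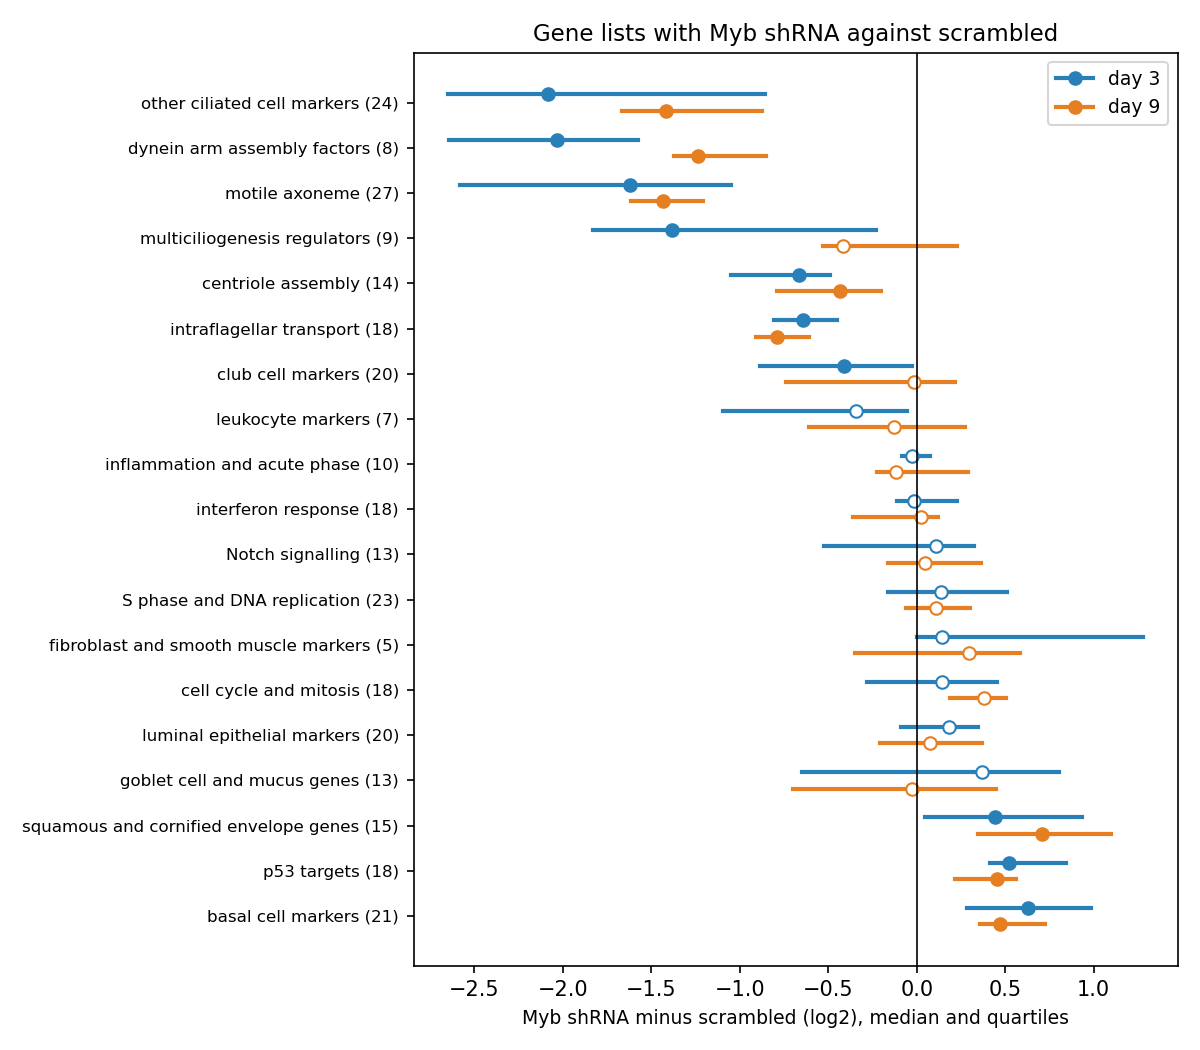
Difference between Myb shRNA and scrambled cultures (log2) for the 19 tested gene lists, with the number of measured genes, at day 3 (blue) and day 9 (orange). Dots are medians over the list's genes, filled where the camera test passed, and lines run between quartiles; motile axoneme medians are -1.62 and -1.43.

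The comparison of day 9 with day 3 in scrambled cultures asks what changes as the control epithelium matures. Ciliary genes rose. Motile axoneme genes rose in 24 of 27 cases (24 adjusted over the list alone), among them Rsph4a, a radial spoke protein, from 8.66 ± 0.64 to 11.14 ± 0.36 and Tppp3 from 10.26 ± 0.06 to 12.04 ± 0.15. Motile axoneme genes had a median of 1.34 (camera adjusted p = 7.23e-18, adjusted p = 0.147 with an estimated correlation). Of 24 other ciliated cell markers, 19 rose and 1 fell (21 and 1 adjusted over the list alone). Other ciliated cell markers had a median of 1.53 (camera adjusted p = 1.75e-19, adjusted p = 0.147 with an estimated correlation). The cadherin-related genes Cdhr4 and Cdhr3 rose by 4.89 ± 0.35 and 3.47 ± 0.33 and Fam183b by 2.24 ± 0.21. Dynein arm assembly factors rose in 6 of 8 cases (7 adjusted over the list alone) and intraflagellar transport genes in 13 of 18 (15 adjusted over the list alone), with Dnajb13 at 1.63 ± 0.24, Ift172 at 2.06 ± 0.28 and Dync2li1 at 1.12 ± 0.12. These assembly factors had a median of 0.97 (camera adjusted p = 7.90e-06, adjusted p = 0.147 with an estimated correlation). Intraflagellar transport genes had a median of 0.82 (camera adjusted p = 5.11e-10, adjusted p = 0.147 with an estimated correlation).

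Regulators of multiciliogenesis did not pass as a list in scrambled cultures (2 of 9 rose and 1 fell, median -0.22, camera adjusted p = 0.864). Ccdc78 rose by 1.42 ± 0.25, and Ccno differed by -0.54 ± 0.22 (adjusted p = 0.113, and 0.0312 with a replicate block). Club cell markers rose in 6 of 20 cases and fell in 2 (7 and 2 adjusted over the list alone), with Scgb1a1 from 8.41 ± 0.12 to 10.09 ± 0.60, the haptoglobin gene Hp by 1.59 ± 0.25 and Bpifa1 by 1.23 ± 0.11. Club cell markers had a median of 0.19 (camera adjusted p = 0.00535, adjusted p = 0.147 with an estimated correlation).

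Basal, squamous, proliferation, p53 and fibroblast lists passed as lower at day 9 with the preset correlation. Basal cell markers fell in 4 of 21 cases (5 adjusted over the list alone), such as Cav1 at -1.02 ± 0.20 and the keratin Krt15 at -0.61 ± 0.13. Basal cell markers had a median of -0.34 (camera adjusted p = 0.0162, adjusted p = 0.518 with an estimated correlation). Without day 3 scrambled replicate 3 the basal list had a median of -0.07 (adjusted p = 0.393). The basal call was also lost with array weights and without the 4 arrays numbered 3. Squamous genes fell in 5 of 15 cases (6 adjusted over the list alone), with Ivl at -1.78 ± 0.37, detected on 2 of 3 day 9 arrays, and Sprr1a, not well above background at day 9, at least 2.19-fold lower (adjusted p = 0.00192). Squamous genes as a list had a median of -0.64 (camera adjusted p = 0.00125, adjusted p = 0.147 with an estimated correlation). Cell cycle genes fell in 5 of 18 cases (10 adjusted over the list alone), with Cdk1 at -0.89 ± 0.15. Cell cycle genes as a list had a median of -0.79 (camera adjusted p = 0.000456, adjusted p = 0.518 with an estimated correlation). S phase genes fell in 2 of 23 (1 adjusted over the list alone), with Rrm1 at -0.69 ± 0.16. S phase genes as a list had a median of -0.39 (camera adjusted p = 0.00825, adjusted p = 0.518 with an estimated correlation). Targets of p53 fell in 8 of 18 cases (8 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at -0.44 ± 0.10. The p53 targets had a median of -0.41 (camera adjusted p = 0.0278, adjusted p = 0.354 with an estimated correlation). The p53 list's call was lost without day 3 scrambled replicate 1 or 2 or day 9 scrambled replicate 2 (adjusted p = 0.0530, 0.0674 and 0.0544). Detection on all 12 arrays lost it too. Fibroblast and smooth muscle markers fell in 3 of 5 cases (3 adjusted over the list alone). Fibroblast and smooth muscle markers had a median of -0.94 (camera adjusted p = 0.0192, adjusted p = 0.147 with an estimated correlation). The smooth muscle actin gene Acta2 fell from 9.95 ± 0.35 to 6.64 ± 0.24, Sparc by 1.30 and Lox by 0.94.

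Further large rises in scrambled cultures were those of Serpinb12 at 4.87 ± 0.48 and Calml4 at 3.44 ± 0.27, each detected on 1 of 3 day 3 arrays, and Diras2 at 4.01 ± 0.47. Others were those of the diamine oxidase Aoc1 at 3.46 ± 0.35, Sec14l3 at 3.35 ± 0.36 and Cfap97d2 at 3.29 ± 0.23. Further large falls were those of the heat shock protein gene Hspa1a at -2.64 ± 0.15, the tight junction gene Cldn6 at -2.40 ± 0.29, Akr1c18 at -2.34 ± 0.23, and Mcam, an adhesion molecule, at -2.20 ± 0.26. In scrambled cultures 1601 genes passed, 896 higher and 705 lower at day 9, and 3033 genes (32.3%) had groups that did not overlap, against 10% by chance. With the replicate block the count was 2817, of which 1340 were higher and 1477 lower, so the balance turned. It was 2747 without day 3 scrambled replicate 3, 810 without day 9 scrambled replicate 3, and 1004 and 910 without day 3 scrambled replicates 1 and 2. Centring the arrays on their 75th percentile in place of quantile normalisation moved the median difference of all genes in this comparison to -0.137. Median, mean and test differed in sign for the regulators and for inflammation.

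The day 9 scrambled arrays enter this comparison and that of the shRNAs at day 9. Across genes the differences of these comparisons had a Pearson correlation of -0.703, against -0.477 in simulated unchanged groups with the same shared arrays, and a covariance of -0.176 against -0.0216. Of the genes past the threshold in each, 578 were higher at day 9 in scrambled and lower with Myb shRNA at day 9, against 84.9 for independent lists, and 223 were lower and then higher, against 46.9. Part of these overlaps may come from the shared arrays. With the day 3 comparison of the shRNAs, which shares the day 3 scrambled arrays, the correlation was -0.318 against 0.479 simulated, and the covariance -0.0924 against 0.0203.

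**Figure D2:**
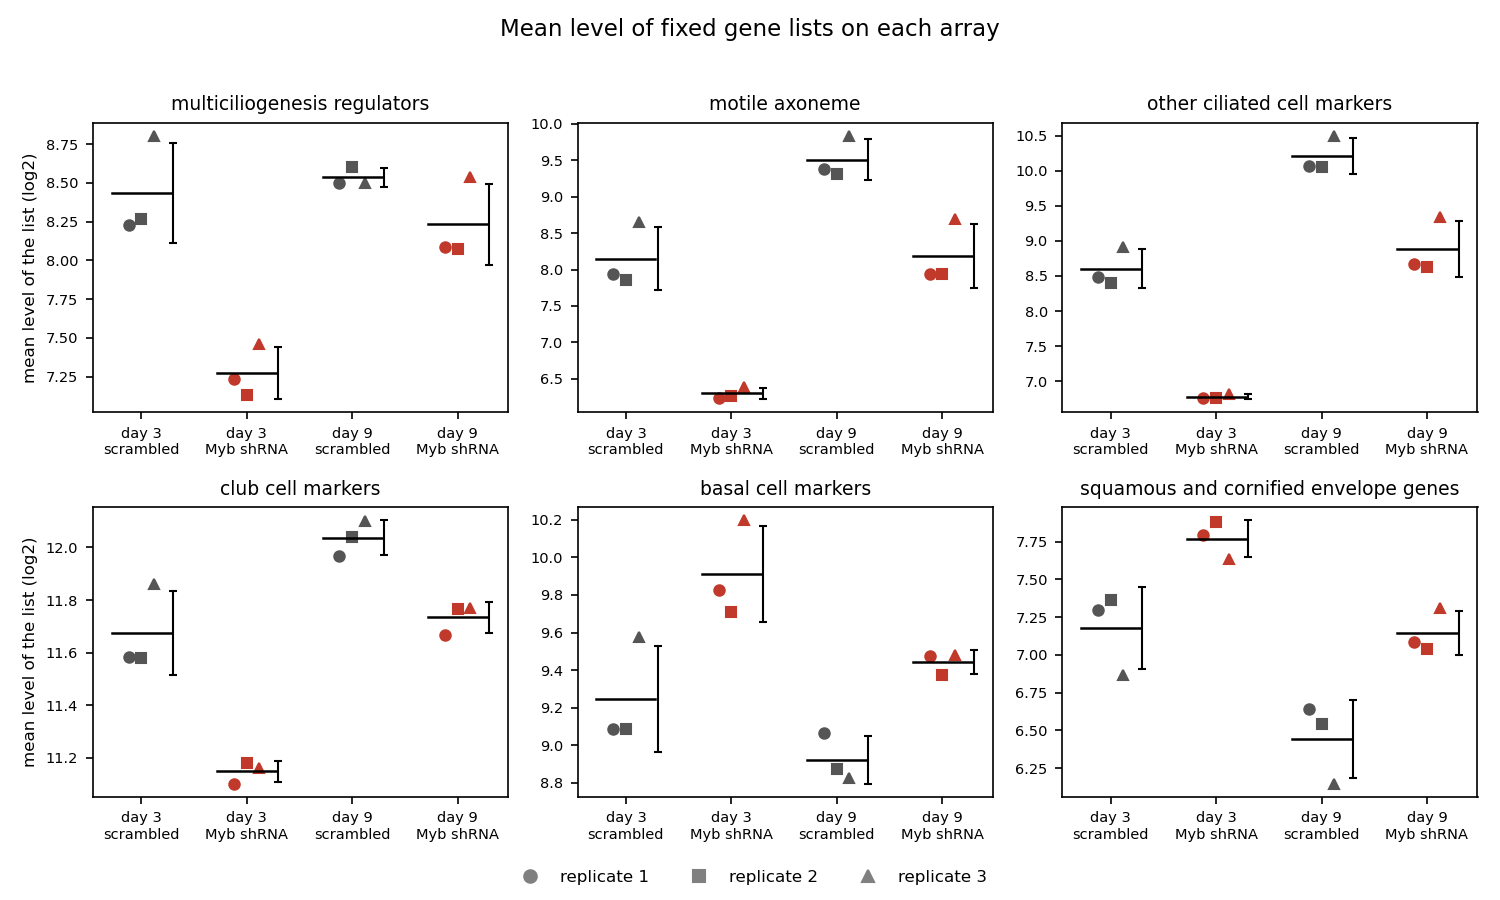
Mean level (log2 intensity) of the genes of 6 lists on each of the 12 arrays, by day, in scrambled (grey) and Myb shRNA (red) cultures. The shape of a dot gives the replicate number, bars are means, error bars are SD over 3 arrays, vertical axes differ, and motile axoneme genes average 8.15, 6.30, 9.51 and 8.19 in day 3 scrambled, day 3 Myb shRNA, day 9 scrambled and day 9 Myb shRNA cultures.

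The comparison of day 9 with day 3 in Myb shRNA cultures asks what changed with time under the shRNA. Regulators of multiciliogenesis rose in 6 of 9 cases (6 adjusted over the list alone). These regulators had a median of 1.35 (camera adjusted p = 0.000899, adjusted p = 0.191 with an estimated correlation). Their call was lost with detection on all 12 arrays. Ccno rose from 10.26 ± 0.25 to 11.83 ± 0.24, and Foxj1, the transcription factor of motile ciliogenesis, and Foxn4 rose by 1.44 ± 0.26 and 1.35 ± 0.26, each detected on 1 of 3 day 3 arrays. Motile axoneme genes rose in 24 of 27 cases (26 adjusted over the list alone), with Tppp3 from 7.65 ± 0.08 to 10.76 ± 0.43, Dynlrb2 by 2.74 ± 0.19 and Dnali1 by 2.62 ± 0.21. Motile axoneme genes had a median of 1.95 (camera adjusted p = 4.72e-24, adjusted p = 0.0929 with an estimated correlation). Other ciliated cell markers rose in 21 of 24 cases (21 adjusted over the list alone), with Fam183b at 3.35 ± 0.21 and Riiad1 at 2.91 ± 0.18. Other ciliated cell markers had a median of 2.42 (camera adjusted p = 5.34e-24, adjusted p = 0.0801 with an estimated correlation). Cdhr3 and Cdhr4, not well above background at day 3, were at least 13.6-fold and 10.9-fold higher (adjusted p = 1.09e-06 and 3.97e-06). Dynein arm assembly factors rose in 7 of 8 cases (7 adjusted over the list alone) and intraflagellar transport genes in 11 of 18 (15 adjusted over the list alone), with Dnaaf1 at 2.96 ± 0.30 and Dync2li1 at 1.13 ± 0.12. These assembly factors had a median of 2.27 (camera adjusted p = 5.41e-10, adjusted p = 0.0801 with an estimated correlation). Intraflagellar transport genes had a median of 0.78 (camera adjusted p = 1.60e-09, adjusted p = 0.112 with an estimated correlation). Centriole assembly genes rose in 2 of 14 cases (1 adjusted over the list alone), with Ccp110 at 1.25 ± 0.23. Centriole assembly genes had a median of 0.30 (camera adjusted p = 0.0159, adjusted p = 0.353 with an estimated correlation). Without day 9 Myb shRNA replicate 3 the centriole list's adjusted p was 0.0676.

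Club cell markers rose with time under the shRNA in 11 of 20 cases and 1 fell (13 and 1 adjusted over the list alone), including Hp from 10.31 ± 0.47 to 12.26 ± 0.51, and the cytochromes P450 Cyp4b1 and Cyp2b10 by 1.14 ± 0.11 and 0.91 ± 0.14. Club cell markers had a median of 0.70 (camera adjusted p = 9.54e-07, adjusted p = 0.0515 with an estimated correlation). Basal cell markers fell in 7 of 21 cases (7 adjusted over the list alone), with Lama3 at -1.29 ± 0.18 and Egfr at -0.98 ± 0.14. Basal cell markers had a median of -0.34 (camera adjusted p = 0.000815, adjusted p = 0.343 with an estimated correlation). Luminal markers fell in 6 of 20 (6 adjusted over the list alone), with Krt19 at -0.80 ± 0.09. Luminal markers had a median of -0.23 (camera adjusted p = 0.0159, adjusted p = 0.194 with an estimated correlation). The luminal call was lost without day 9 Myb shRNA replicate 3 (adjusted p = 0.0536), and also with percentile centring and with array weights. Squamous genes fell in 4 of 15 cases (1 higher and 5 lower adjusted over the list alone), with Sprr1a from 9.09 ± 0.15 to 6.28 ± 0.43 and Ivl by 2.39. Squamous genes as a list had a median of -0.37 (camera adjusted p = 0.00334, adjusted p = 0.112 with an estimated correlation). The squamous call was lost with detection on all 12 arrays. Targets of p53 fell in 9 of 18 with 1 higher (11 and 1 adjusted over the list alone), with Zmat3 at -0.85 ± 0.16. The p53 targets had a median of -0.51 (camera adjusted p = 6.96e-05, adjusted p = 0.0863 with an estimated correlation). S phase genes fell in 2 of 23 cases (2 adjusted over the list alone), with Mcm10 at -1.05 ± 0.24, detected on 1 of 3 day 9 arrays. S phase genes as a list had a median of -0.36 (camera adjusted p = 0.0027, adjusted p = 0.353 with an estimated correlation). Without day 9 Myb shRNA replicate 3 the S phase list's adjusted p was 0.0559. The S phase call was also lost without the 4 arrays numbered 3. Fibroblast and smooth muscle markers fell in 4 of 5 cases (4 adjusted over the list alone), with Acta2 at -2.52 ± 0.40, Lox at -1.92 ± 0.21 and Sparc at -1.71 ± 0.19. Fibroblast and smooth muscle markers had a median of -1.71 (camera adjusted p = 0.000102, adjusted p = 0.0515 with an estimated correlation).

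Other large changes under the shRNA were the rises of Prr29 at 3.44 ± 0.19, Cfap299 at 3.27 ± 0.24, Sec14l3 at 3.18 ± 0.36 and Mdh1b at 3.14 ± 0.22. Falls were those of Cldn6 at -3.63 ± 0.29, Mcam at -2.84 ± 0.26, the fibronectin gene Fn1 at -2.83 ± 0.31 and Sox11, a transcription factor gene, at -2.65 ± 0.44. In Myb shRNA cultures 1566 genes passed, 869 higher and 697 lower at day 9, and 3259 genes (34.7%) had groups that did not overlap, against 10% by chance. The count was 2367 with the replicate block (1249 higher and 1118 lower) and 1039 without day 3 Myb shRNA replicate 1. Median, mean and test differed in sign for the Notch, interferon and inflammation lists. Across genes the changes with time in both arms, which share no array, had a Pearson correlation of 0.675 and a Spearman correlation of 0.513. Of the genes past the threshold, 506 rose in both arms against 83.0 for independent lists, and 262 fell in both against 52.4.

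The interaction of day and shRNA asks whether the difference between the shRNAs itself changed from day 3 to day 9. Positive values mean a less negative or more positive difference at day 9. The endothelial diaphragm gene Plvap went from 6.63 ± 0.33 with Myb shRNA against 9.19 ± 0.34 in scrambled at day 3 to 9.25 ± 0.09 against 8.24 ± 0.30 at day 9, an interaction of 3.56 ± 0.29 (adjusted p = 0.000121). Shisa8 followed at 3.24 ± 0.35 with 2 of 3 day 3 Myb shRNA arrays detecting it. Of the regulators of multiciliogenesis, 3 of 9 had a positive interaction (4 adjusted over the list alone). Ccno, lower with the shRNA at day 3, stood at 11.83 ± 0.24 against 11.55 ± 0.24 at day 9 (interaction 2.11 ± 0.31, adjusted p = 0.00579), and Foxn4 had 2.15 ± 0.37 (adjusted p = 0.0112). Ciliary genes with positive interactions included Lrrc23 at 2.43 ± 0.35, Morn5 at 2.02 ± 0.24, Zmynd10 at 1.94 ± 0.32 and Dynlrb2 at 1.69 ± 0.26. Outside the ciliary lists the histidine decarboxylase gene Hdc had 1.84 ± 0.27 and Cdk1 1.28 ± 0.21. Negative interactions included Clca3b at -2.79 ± 0.43, Timp4, a metalloproteinase inhibitor, at -2.32 ± 0.33, the transcription cofactor gene Lbh at -2.26 ± 0.39, the ribonuclease gene Rnase4 at -2.15 ± 0.37 and the semaphorin receptor gene Nrp1 at -2.06 ± 0.25. Of these, Foxn4, Zmynd10, Timp4 and Nrp1 lay near background on some arrays of at least 1 group. Timp4 was detected on no day 3 Myb shRNA array and Nrp1 on no day 9 scrambled array, so the sizes of their interactions are not fixed.

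As lists, motile axoneme genes had a median interaction of 0.36 (6 of 27 genes passed, 10 adjusted over the list alone, camera adjusted p = 8.00e-05, adjusted p = 0.583 with an estimated correlation). Dynein arm assembly factors had 0.84 (1 of 8, 4 adjusted over the list alone, camera adjusted p = 0.000376, adjusted p = 0.361 with an estimated correlation) and the regulators 0.48 (camera adjusted p = 0.00292, adjusted p = 0.361 with an estimated correlation). Other ciliated cell markers had a median of 0.37 (4 of 24, 10 adjusted over the list alone, camera adjusted p = 0.00292, adjusted p = 0.625 with an estimated correlation). That call was lost without day 3 scrambled replicate 3 or day 9 Myb shRNA replicate 3 (adjusted p = 0.0692 and 0.145). It was also lost without background correction (median -0.01, adjusted p = 0.111), with the submitters' values (0.03, adjusted p = 0.0717), with array weights (0.07, adjusted p = 0.243) and without the 4 arrays numbered 3 (0.14, adjusted p = 0.0527). Club cell markers had 0.31 (1 of 20, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.361 with an estimated correlation). The club cell call was lost without any of 5 arrays: day 3 scrambled replicate 3, day 3 Myb shRNA replicate 1, day 9 scrambled replicate 1, and day 9 Myb shRNA replicates 2 and 3 (adjusted p = 0.238, 0.0638, 0.111, 0.0595 and 0.0642). It was also lost with detection on all 12 arrays, with array weights and without the 4 arrays numbered 3 (medians 0.27, 0.26 and 0.23, adjusted p = 0.0954, 0.0849 and 0.0639). Goblet cell and mucus genes had a median of -0.36 (1 of 13 lower, 4 adjusted over the list alone, camera adjusted p = 0.00474, adjusted p = 0.384 with an estimated correlation), a call lost without a filter, where the median was -0.02 (adjusted p = 0.122), and with detection on all 12 arrays (median -0.24, adjusted p = 0.0954). With array weights the axoneme, dynein and regulator calls were lost too, with medians down to 0.13, 0.50 and 0.12 (adjusted p = 0.0849 for each). That of the regulators was also lost with detection on all 12 arrays (median 0.15, adjusted p = 0.0954). Intraflagellar transport genes did not pass (median -0.07, 0 of 18 genes, 1 higher adjusted over the list alone, camera adjusted p = 0.830). Nor did centriole assembly genes (median 0.29, 0 of 14 genes, 1 higher adjusted over the list alone, camera adjusted p = 0.0846). Fry, which asks whether a list's genes move on balance one way, passed none of the 19 lists.

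In all, 155 genes passed the interaction, 70 higher and 85 lower, or 1330 at an unadjusted p under 0.05. With the replicate block 715 passed, 329 higher and 386 lower. Without the block the count was 329 without day 3 scrambled replicate 3, 52 without day 3 Myb shRNA replicate 1, and 97 without day 3 scrambled replicate 2. Without day 9 scrambled replicates 1, 2 and 3 it was 86, 92 and 84, and without day 9 Myb shRNA replicates 1 and 2 it was 92 and 63. Median, mean and test differed in sign for the squamous, Notch and S phase lists, none of which passed.

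**Figure D3:**
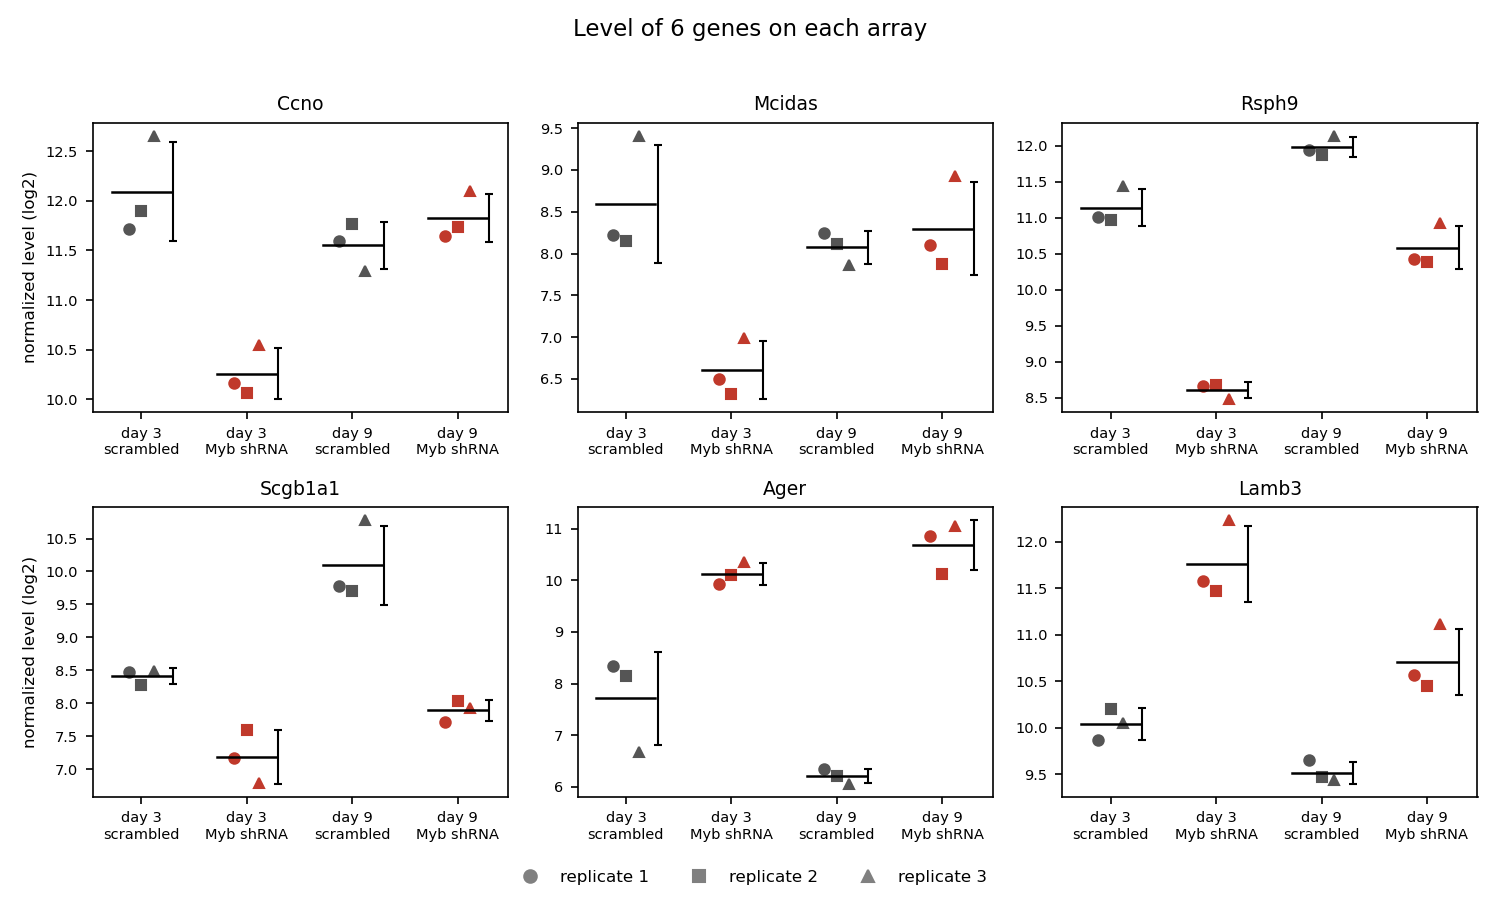
Levels (log2 intensity) of Ccno, Mcidas, Rsph9, Scgb1a1, Ager and Lamb3 on each of the 12 arrays, by day, in scrambled (grey) and Myb shRNA (red) cultures. The shape of a dot gives the replicate number, bars are means, error bars are SD over 3 arrays, vertical axes differ, and Ccno means are 12.09 and 10.26 at day 3 and 11.55 and 11.83 at day 9 in scrambled and Myb shRNA cultures.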

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

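The difference between Myb shRNA and scrambled cultures was tested for a change between day 3 and day 9, and the 20 genes and 6 lists below are the largest interactions that passed at an adjusted p under 0.05 (limma, n = 3 per group). Of the tests in this part, that of a later onset was chosen only after the result was seen. Positive interactions (log2) were found for Plvap 3.56, Shisa8 3.24, Ccna1 2.53, Lrrc23 2.43, Mcidas 2.21, Foxn4 2.15, Ccno 2.11, Morn5 2.02, Zmynd10 1.94 and Hdc 1.84. Negative ones were found for Clca3b -2.79, Muc16 -2.40, Timp4 -2.32, Dkk3 -2.32, Lbh -2.26, Rnase4 -2.15, Pcbd1 -2.09, Nrp1 -2.06, Ly6c1 -2.02 and Synm -1.90. Median interactions of the lists were 0.484 for regulators of multiciliogenesis, 0.360 for motile axoneme genes, 0.841 for dynein arm assembly factors, 0.366 for other ciliated cell markers, 0.307 for club cell markers and -0.361 for goblet cell and mucus genes. With an estimated correlation the lists' adjusted p were 0.361, 0.583, 0.361, 0.625, 0.361 and 0.384, so no list passed. Without a detection filter the median of the goblet cell and mucus genes was -0.0152, and with array weights those of the regulators and the axoneme genes were 0.117 and 0.134.

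The positive genes were all lower with Myb shRNA at day 3, and less so, or not lower, at day 9. Mcidas stood at 8.59 and 6.61 in scrambled and Myb shRNA cultures at day 3 and at 8.07 and 8.30 at day 9, and Ccna1 at 8.68 and 4.94 and then 8.83 and 7.61. The negative genes differ in kind. Clca3b, Timp4, Lbh, Rnase4 and Synm rose with time in scrambled cultures and had lower time differences under the shRNA. Lbh went from 8.01 to 10.92 in scrambled and from 8.15 to 8.80 with the shRNA. Nrp1 was at 7.83 in day 3 Myb shRNA cultures only, against 5.48, 5.10 and 5.38 elsewhere. Ccna1 was at background on all day 3 Myb shRNA arrays, Muc16 on all day 3 scrambled arrays, and Pcbd1, Timp4, Nrp1 and Synm in some groups, so the sizes of these interactions are not fixed.

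Calls for 5 of these genes were lost when single arrays were left out. Mcidas had an adjusted p of 0.0970 and 0.0720 without day 3 Myb shRNA replicates 1 and 2, 0.0549, 0.0669 and 0.0780 without day 9 scrambled replicates 1, 2 and 3, and 0.0530 without day 9 Myb shRNA replicate 1. Muc16 had 0.0524 without day 3 scrambled replicate 2, 0.0731 without day 3 Myb shRNA replicate 1, 0.0564 without day 9 scrambled replicate 3, and 0.0533 and 0.0634 without day 9 Myb shRNA replicates 1 and 2. Dkk3 had 0.0578 and 0.0525 without day 3 Myb shRNA replicate 1 and day 9 Myb shRNA replicate 2. Ly6c1 had 0.0660 and 0.0559 without day 3 Myb shRNA replicates 1 and 2, 0.0527 and 0.0611 without day 9 scrambled replicates 1 and 3, and 0.0693 without day 9 Myb shRNA replicate 2. Synm was lost without any of 8 arrays, with 0.0607 and 0.0908 without day 3 scrambled replicates 1 and 2, 0.109 and 0.0859 without day 3 Myb shRNA replicates 1 and 2, 0.0549 and 0.0636 without day 9 scrambled replicates 1 and 3, and 0.0833 and 0.1001 without day 9 Myb shRNA replicates 1 and 2.

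By camera at the preset correlation, 3 ciliated cell lists (motile axoneme, dynein arm assembly and other ciliated cell markers) differed less between the shRNAs at day 9 than at day 3. Intraflagellar transport genes did not (median interaction -0.07, camera adjusted p = 0.830), and fry passed none of the lists. The call of the other ciliated cell markers was lost in 8 of 24 alternatives, among them no background correction, the submitters' values, array weights and leaving out the 4 arrays numbered 3 (adjusted p = 0.111, 0.0717, 0.243 and 0.0527). If the smaller difference is real, it could have several causes. Compression of bright signals at day 9 would leave little interaction among dimmer genes. The 18 list members detected on all arrays with a day 9 scrambled level under 11 had a median interaction of 0.916 (95% bootstrap interval 0.228 to 1.304). That level enters the interaction with a minus sign, so choosing genes where it is low favours a positive value. Compression therefore stays undecided. The bootstrap intervals in this paragraph resample genes and not arrays, so they leave out the spread between cultures. Without the 4 arrays numbered 3 the median interaction of the 3 lists was 0.259, against 0.455 with all 12 arrays. By the bound set beforehand, 0.5 of the latter, these arrays would not be the cause, but a bootstrap interval of the difference, -0.166 to 0.316, was added after the value was seen and leaves it undecided. A later onset under the shRNA would leave day 9 Myb shRNA cultures near day 3 scrambled ones, and the median difference between them over 59 genes was 0.0818 (interval 0.00493 to 0.134). A lasting partial reduction could leave the same values, so a later onset stays open.

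The count of 155 interaction genes was set against relabelings of the shRNA within each day, drawn at random from 200, with the additive shRNA effect removed first. The interaction itself was not removed, so relabelings that mix the real groups hold it as spread. Of 100 relabelings, the real one included, 3 gave as many genes. The others gave 2521 and 1603, and the next 1. Both set the arrays numbered 3 apart, with none of them relabeled scrambled at day 3 and both of them at day 9. Other drawn relabelings that did the same gave 0 genes. This trait alone therefore does not account for the high counts, whose cause was not tested. The relabelings were drawn 3 times, with 2, 3 and 2 of 100, and the least favourable draw is the one given.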

How the results depend on the processing

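Each result was fitted again under the alternatives, and the named gene and list calls were compared with the first fit. Of 353 gene calls and 48 list calls, 347 and 47 were kept without background correction, 346 and 47 with the submitters' values, 346 and 47 with percentile centring, 335 and 47 without a filter, 344 and 48 with the mean of probes, 344 and 48 without a trend and 351 and 40 with array weights. Detection on all 12 arrays kept 240 of 246 gene calls and 34 of 41 list calls, with 80 interaction genes, 63.8% of them higher. The mean of probes reversed 1 gene: Lyz1, day 9 against day 3 in scrambled, was at -0.229 (adjusted p = 0.466) against 0.68 (adjusted p = 0.0452), and it gave -0.103 for Myb at day 9. Array weights gave 2742 and 6564 genes for the shRNAs at day 9 and day 3, 4673 and 4777 for the days in scrambled (44.0% higher) and Myb shRNA, and 3399 for the interaction, with 1 interaction list, and the cause was not tested. A 2-fold minimum left 526, 578, 470 and 496 genes in the 4 comparisons of groups. Of these, 121 were higher and 405 lower for the shRNAs at day 9, and 244 and 334 at day 3. For the days, 402 were higher and 68 lower in scrambled, and 322 and 174 in Myb shRNA. Fits of only the 6 arrays of the groups compared gave 1637, 1553, 1081 and 1600. Camera with an estimated correlation, taken from the fit without the replicate block, passed 0 lists in each of the 5 comparisons. Fry kept 37 of 48 list calls, with 9, 13, 8, 12 and 0 lists.

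The replicate number as a block gave 2331, 3400, 2817, 2367 and 715 genes for the shRNAs at day 9 and day 3, the days in scrambled and Myb shRNA, and the interaction. Of the genes that passed without the block, 1513, 2134, 1601, 1565 and 155 passed with it. It kept 353 of 353 named gene calls and 48 of 48 list calls, and 57 named genes were gained. Without the 4 arrays numbered 3 the counts were 2404, 3596, 3518, 2482 and 1410, with 344 gene calls and 44 list calls kept. A block by slide was not run, because the slide is not given in the sources used here.

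Leaving out each array in turn kept 315 to 346 gene calls and 43 to 48 list calls. The shRNAs at day 9 gave 948 genes (without day 9 scrambled replicate 3) to 1900 (without day 3 scrambled replicate 3), 36.3% to 44.8% higher, and 8 to 11 lists. The shRNAs at day 3 gave 1440 (without day 3 Myb shRNA replicate 3) to 3022 (without day 3 scrambled replicate 3), 45.5% to 52.4% higher, and 10 to 11 lists. The days in scrambled gave 810 (without day 9 scrambled replicate 3) to 2747 (without day 3 scrambled replicate 3), 69.5% and 48.9% higher, and 10 to 12 lists. In Myb shRNA they gave 1039 (without day 3 Myb shRNA replicate 1) to 1980 (without day 3 scrambled replicate 3), 54.9% to 60.1% higher, and 10 to 14 lists. The interaction gave 52 (without day 3 Myb shRNA replicate 1) to 329 (without day 3 scrambled replicate 3), 41.2% to 61.5% higher, and 4 to 10 lists, the latter without day 3 scrambled replicate 1. The Myb difference ranged from -0.0571 to 0.146 at day 9 and from -0.465 to -0.334 at day 3. Genes near background, such as Myb itself, have fold changes that these arrays compress.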

Other observations

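Of the tests in this part, that of basal against club cell markers and those of fibroblasts and off-target effects were chosen only after the result was seen, while the alveolar list and the tests of the arrays numbered 3 were fixed before their values were looked up. Ager, a receptor of alveolar type 1 cells, and Col4a3, a collagen of alveolar and kidney basement membranes, were among the largest rises with Myb shRNA, which led to a test of 26 other markers of that cell type, none of them in a list above. Of 19 that were measured, 11 rose and none fell at day 9 (median 0.70, camera p = 7.36e-11; p = 0.00757 with an estimated correlation), and 10 rose and 1, Cav2, fell at day 3 (median 0.73, camera p = 1.088e-06; p = 0.0292 with an estimated correlation). Emp2, a membrane protein, rose from 10.57 to 12.09 at day 9 and from 11.39 to 12.57 at day 3. Gprc5a rose by 1.26 ± 0.11 at day 9 and 0.84 at day 3, and Col4a4 by 1.48 ± 0.22 and 1.55. Flrt3 rose by 1.06 at day 9 and 1.34 at day 3, and Lmo7 by 1.02 and 0.90. Clic5, on no scrambled array at day 9 above detection, was at least 1.89-fold higher there. At day 3 its log2 difference was 1.01, with 1 of 3 scrambled arrays detecting it. Aqp5, a water channel, rose by 0.48 ± 0.08 at day 9 from the highest level of the list and differed by 0.04 at day 3 (adjusted p = 0.760), and Hopx rose by 0.93 at day 3 (adjusted p = 0.0353) and differed by 0.50 at day 9 (adjusted p = 0.298). The difference between the days passed for neither gene (adjusted p = 0.0563 and 0.676). Of the 19, Vegfa, Spock2, Gramd2, Dpysl2 and Limch1 passed at neither day, though with a replicate block Spock2 and Limch1 did at day 3 (adjusted p = 0.0112 and 0.0376). Since 16 of the 19 were detected on all day 9 scrambled arrays, most of the list is expressed in the tracheal culture without the Myb shRNA. Which cells hold the rise is open, a flat or squamous-like state among the possibilities. Staining for Ager and Emp2 together with Krt4 or Ivl would tell whether 1 cell type holds them.

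In scrambled cultures the same list fell with time (1 member rose and 6 fell; median -0.25, camera p = 0.00798; p = 0.187 with an estimated correlation). The test of the difference between days, for the list, gave a median of 0.10 and did not pass (camera p = 0.0811; p = 0.371 with an estimated correlation).

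Day 9 Myb shRNA cultures were also set against day 3 scrambled ones, a comparison added after the others were seen. It gave 769 genes, 386 higher and 383 lower. Ager at 2.96, Cdhr4 at 2.81 and the cystine transporter gene Slc7a11 at 1.94 were higher in day 9 Myb shRNA cultures, and Dmbt1 at -3.01, Gp2 at -2.89 (1 of 3 day 9 arrays detecting it) and Acta2 at -2.74 were lower. Centriole assembly was the only fixed list that passed (median -0.37, camera adjusted p = 0.00482; adjusted p = 0.956 with an estimated correlation), while motile axoneme genes had a median of 0.00581 (camera adjusted p = 0.929). A culture series that also runs past day 9 would test a delay. With a delay, ciliated cell genes under the shRNA would reach the scrambled levels at a later day, while a lasting partial reduction would keep them lower.

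Basal, squamous and p53 lists passed as higher with Myb shRNA at both days by camera at the preset correlation. With an estimated correlation none of them passed (adjusted p = 0.281, 0.155 and 0.170 at day 9 and 0.171, 0.146 and 0.146 at day 3). The correlation was estimated without the replicate block, so it includes the deviation that the arrays numbered 3 share. Fry passed these lists as higher, with adjusted p = 0.0162, 0.00188 and 0.00418 at day 9 and 0.00292, 0.00204 and 0.000465 at day 3. If the differences are real, they may have causes other than a change within basal cells. A loss of ciliated cells alone would raise the share of every other cell type alike. Yet at day 9 the basal median (0.469) exceeded the club cell median (-0.0157) by 0.485 (95% bootstrap interval 0.269 to 1.074). The interval resamples genes and not arrays, so it leaves out the spread between cultures. By array, basal markers averaged 9.06, 8.87 and 8.83 in scrambled and 9.48, 9.37 and 9.48 with Myb shRNA. Club cell markers averaged 11.97, 12.04 and 12.10 against 11.67, 11.77 and 11.77. These averages went opposite ways without overlap of the arrays. The club cell list was mixed, however, with 3 of 20 markers higher and 6 lower. It did not pass by camera (adjusted p = 0.174). The values thus go against an equal rise of basal and club cell markers through a loss of ciliated cells alone. Whether the shares of several cell types changed was not tested. Whether fibroblasts contribute is undecided. Of the 6 Myb shRNA arrays, 0 detected any of 5 probes of the collagen genes Col1a1, Col1a2 and Col3a1, but no scrambled array did so either, and nothing shows that these probes work here. Other markers went both ways: Sparc rose by 1.98 at day 3 and 1.56 at day 9 and Lox by 1.28 at day 3, while Acta2 differed by -0.22 at day 3 (adjusted p = 0.729) and Dcn stood at 7.63 in both arms at day 3 and was at 6.94 against 7.49 at day 9 (adjusted p = 0.0625, and 0.0257 with a replicate block). An effect of the shRNA on other targets is undecided, as the labels name no further Myb shRNA. The smaller adjusted p of Myb was 0.0935 in the fit of all genes without the filter (0.138 in a fit of all probes). A further shRNA, or rescue with a resistant Myb, would decide whether other targets are involved.

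The arrays numbered 3 deviated from their group means together, in all groups. If noise of dim probes were the cause, bright genes would not share it, but over the upper part of levels the deviations correlated at 0.578 (lowest and highest of 6 pairs 0.420 and 0.695). If these cultures were further along the change from day 3 to day 9, the deviations would follow that change as measured in the other arm, and the lowest of 4 correlations was 0.185, the others being 0.217, 0.268 and 0.473. With the change taken from arrays numbered 1 and 2 alone, they were 0.210 to 0.468. These correlations are what the explanation needs, and they are modest. List levels on the day 3 arrays numbered 3 went both ways. Motile axoneme genes, which rise with time, were at 8.65 against 7.94 and 7.86 in scrambled and 6.39 against 6.24 and 6.27 with Myb shRNA. Basal cell markers, which fall with time, were higher too, at 9.57 against 9.08 and 9.09 and at 10.20 against 9.83 and 9.71. Other causes were not tested, and the labels do not state that arrays with 1 number share a preparation. Genes are not independent replicates here, and a new set of preparations sampled daily would test it.

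Splits of the 6 arrays of each comparison into other groups of 3 number 10 with the real one and are too few to give a share under 0.05. In each of the 4 comparisons of groups, 1 of 10 splits, the real one, gave as many genes (1513, 2134, 1601 and 1566), and the highest other count was 0, as it was among the splits that part all arrays with the same number. The real difference was not removed first, so every other split mixes the real groups and holds that difference as spread. A count of 0 there therefore says nothing on chance calls. For the interaction, 3 of 100 relabelings gave as many genes as the real 155, with 2521 as the highest other. There only the additive shRNA effect was removed, so relabelings that mix the real groups hold the interaction as spread. The share of 3 of 100 therefore does not measure chance calls.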
